A study of Homo sapiens with 159 samples.

How the data were processed

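The data were Affymetrix U133A arrays of RNA from pediatric B-progenitor acute lymphoblastic leukemia at diagnosis, 1 per sample. Per the labels, RNA was extracted with Trizol from cryopreserved marrow or blood, and samples with fewer than 80% blasts were sorted before extraction. The deposited values are probe set intensity signals on a linear scale, which the authors computed with MAS5 per the submitters' processing notes, whose version is not given in the sources used here. After trimming 2% of the values at each end, the mean signal of every array was 500.1 or 500.2, so the arrays had been scaled to a common mean before they were deposited. Signals ran from 0.2 to 228888, and the median signal of an array from 161 to 347 (median 230). No value was missing. The highest correlation between any pair of arrays was 0.94 and 0 pairs were identical.

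Samples were grouped by the name in their title, which also carries a number within the group. The 22283 probe sets included 68 controls. The platform annotation gave 19065 probe sets 1 gene, 1043 several genes and 2107 none, and probe sets with several or no genes were not used. Of those with 1 gene, 19053 were matched to a RefSeq gene table (assembly GRCh38.p14) by gene number, and 31 sex-linked probe sets were left out. For each of 11939 genes the probe set with the highest mean was kept. A gene was tested if it lay above the 40th percentile of its array in at least 7 samples, which kept 10856 genes and left out 1083. Genes named in the design but left out of that table were not analysed here.

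Tests used limma 3.58.1 in R 4.3.3 on log2(signal + 32). A linear model held the 8 group means, with the variance moderated by eBayes with trend and robust settings. Each group was compared with the equal-weight mean of the other 7, Hyperdip>50 with Hyperdip47-50, and BCR-ABL with the mean of Hyperdip47-50, Pseudodip and Other, in 10 comparisons. There were also 2 moderated F tests, over all 8 groups and over those 3. Tests of a difference between groups or of a correlation were two-sided, p-values were adjusted by Benjamini and Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. A second count asked for a difference of at least 2-fold. No batch was named in the labels used here.

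Of 28 gene lists, 27 were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. The remaining list held MEIS1 and PBX3 as its only 2 measured members. The smallest list size for camera, 5 members, was set after the list sizes were seen. Members were counted as called over all genes and adjusted over the list alone. The genes of 23 chromosomes (10849 genes) were tested in the same way, with chromosomes taken from the RefSeq table. The groups, comparisons, tests, lists, the rule for named genes and all alternatives but 1 were chosen before the data were examined. That rule took the 6 largest rises and 6 largest falls among called genes, or 4 and 4 for Hyperdip47-50, Pseudodip, Other and BCR-ABL against 3 groups. It also took the 4 genes with the smallest p of each F test, up to 3 members of each called list, up to 2 of each chromosome called in Hyperdip>50 or Hypodip, and a few genes fixed by name. All 6 higher genes in Hypodip were within this rule.

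The alternatives were a pseudocount of 1 or 128, no filter or the 60th percentile, quantile normalization, median centring, every probe set or the mean over probe sets, eBayes without trend or robust, array weights, the label number as a block, all other samples pooled, and leaving out each Hypodip sample. Further ones added the 3' to 5' ratios of the GAPDH and ACTB controls, or the mean levels of T cell, monocyte, erythroid and neutrophil markers, as covariates. Leaving out 3 arrays whose median correlation with the others was 0.72 or less, against 0.76 or more for the rest, was added after the data were seen. These arrays were Hyperdip>50 replicate 1, Hyperdip47-50 replicate 10 and BCR-ABL replicate 7. Lists and chromosomes were run with the pseudocounts, quantile normalization, the mean over probe sets, the label number, the marker scores, an estimated correlation and without these arrays, and chromosomes 9 and 20 without each Hypodip sample too. The other alternatives were not run for them.

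The procedure was tested on simulated data with 10856 genes, of which 50 were changed at each of 4 sizes. For a log2 change of 1 it recovered 84% of the changed genes in Hypodip, 82% in MLL, 92% in BCR-ABL, 94% in Hyperdip47-50, 96% in Pseudodip and 98% in Other, and 100% in TEL-AML1 and Hyperdip>50. For a log2 change of 0.5 it recovered between 12% (Hypodip) and 74% (Hyperdip>50). The share of false calls lay between 1.06% and 2.86%. Residuals were shuffled over all samples in 1 draw per group, which gives every group the same spread. These shares therefore need not hold for the real groups, whose spreads can differ. Group labels were also reassigned at random in 100 splits, the real one included. Explanations were tested for 4 patterns and 3 of them are weighed, since the pattern of lower erythroid and cell cycle genes in BCR-ABL was replaced by that of ASMTL and CRLF2 after its tests had been seen. For the replaced pattern, the rule that read the cell cycle test was changed after its value was known.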

Results

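Gene expression was measured on Affymetrix U133A arrays in pediatric B-progenitor acute lymphoblastic leukemia samples taken at diagnosis, each on 1 array. The labels put them in 8 groups. There were 34 samples labelled TEL-AML1 (a fusion that joins ETV6), 20 BCR-ABL (the Philadelphia fusion), 13 MLL (rearrangement of KMT2A), 28 Hyperdip>50, 16 Hyperdip47-50 and 7 Hypodip. Another 16 samples were labelled Pseudodip and 25 Other. The names with a chromosome number give the number counted in the leukemic cells, and Hypodip the cases with fewer chromosomes than normal. The labels do not spell out Pseudodip. Nothing in the labels used here ties samples to donors beyond a number within each group, so p-values measure the spread between these samples. The median signal of an array lay between 161 and 347, and the number of arrays per group limits the precision. Values below are differences on the log2(signal + 32) scale with their standard error (SE), which understates the change of weakly expressed genes. Each SE and limma p-value rests on 1 spread per gene shared by all 8 groups, not on that of the group described. Where a group varies more than the others, its SE is therefore too small. A gene far higher in 1 group also raises the reference of each other group, which enlarges falls and shrinks rises there. Of 10856 genes tested, 4019 differed among the 8 groups by limma's moderated F test at a Benjamini-Hochberg adjusted p under 0.05. The 4 genes with the smallest p were WBP1L, KCNN1 (a potassium channel subunit), ARHGEF4 and PCLO, all highest in TEL-AML1. The mean log2 signal of WBP1L was 11.57 in TEL-AML1 and between 9.99 and 10.23 in the other groups. The 3' to 5' log2 ratio of the ACTB control probe sets, a sign of RNA quality, averaged 1.04 ± 0.66 (SD, n = 28) in Hyperdip>50. The lowest group mean was 0.53 ± 0.26 (SD, n = 16) in Pseudodip. The difference among the 8 groups had a permutation p of 0.0486 for ACTB and 0.0832 for GAPDH, and an adjusted p of 0.0832 for both.

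**Figure D1:**
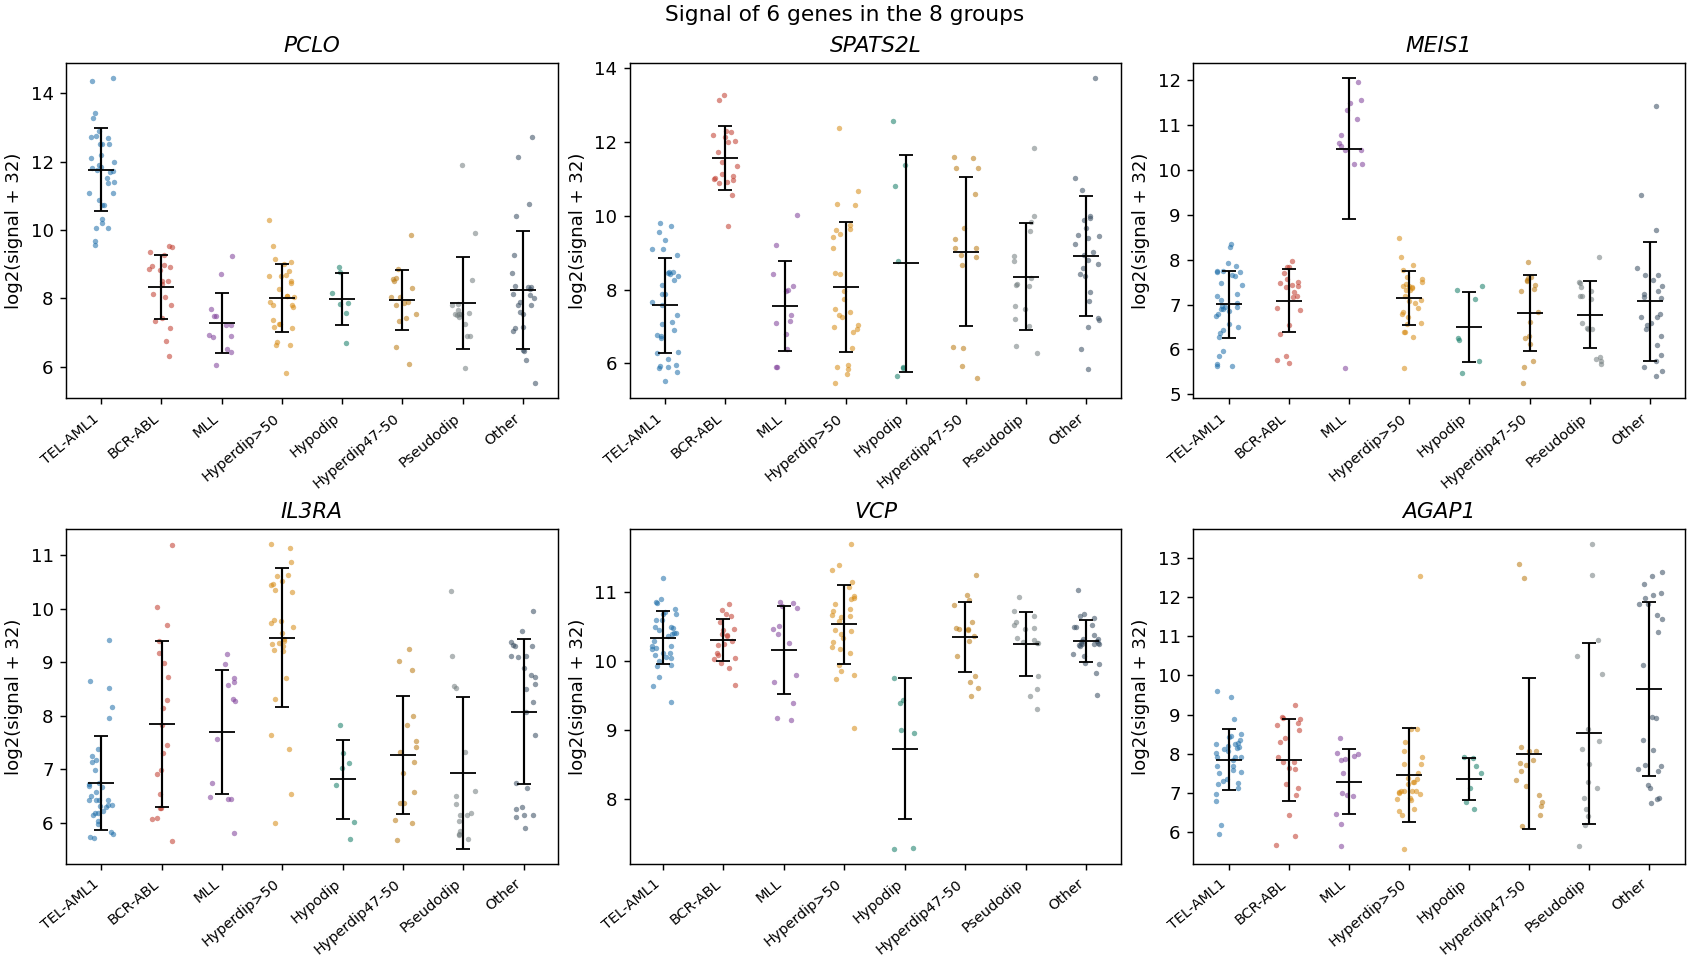
Log2(signal + 32) of 6 genes in the 8 groups, with 1 point per sample and a bar at the group mean with the SD as error bar. PCLO was highest in TEL-AML1, SPATS2L in BCR-ABL, MEIS1 in MLL, IL3RA in Hyperdip>50 and AGAP1 in Other by group mean, and VCP was lowest in Hypodip.

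TEL-AML1 samples were set against the mean of the other 7 groups to ask which genes mark this fusion. PCLO, a presynaptic scaffold, was 14.0-fold higher (log2 difference 3.81 ± 0.23, n = 34), and TNFRSF21, a death receptor, 11.0-fold higher (3.47 ± 0.30). TCFL5, a helix-loop-helix transcription factor, rose by 3.46 ± 0.21, ARHGEF4, a guanine exchange factor, by 3.22 ± 0.20, SMAD1, which carries BMP signals, by 2.84 ± 0.38, and GNG11 by 2.80 ± 0.34. These 6 genes were above the median of the other samples in 34 of 34 TEL-AML1 samples each. The largest falls were in the surface protein CD9 (-2.13 ± 0.35), MAPKBP1 (-2.12 ± 0.25), the lysosomal ATPase ATP13A2 (-2.06 ± 0.19), the galectin LGALS1 (-1.98 ± 0.36), the prostaglandin receptor PTGER4 (-1.96 ± 0.25) and the hyaluronan receptor CD44 (-1.87 ± 0.17). The reference includes MLL, where LGALS1 was far higher, which enlarges the LGALS1 fall.

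Limma called 2478 of 10856 genes at an adjusted p under 0.05, 1168 higher and 1310 lower, of which 161 and 72 differed at least 2-fold. All 14 measured genes of the list reported for TEL-AML1 rose (14 when adjusted over the list alone, camera adjusted p = 1.25e-49, adjusted p = 9.12e-14 with an estimated correlation), among them KCNN1 at 2.35 ± 0.14. This list and those for BCR-ABL and MLL come from general knowledge of earlier reports, whose samples can overlap with these, so their counts here and below are not independent evidence. Of 12 MHC class II genes, which present antigen to T cells, 9 rose (10 adjusted over the list alone, camera adjusted p = 2.90e-06), led by HLA-DOB at 1.73 ± 0.24 and HLA-DMB at 0.86 ± 0.15. The list had an adjusted p = 0.168 with an estimated correlation. Folate and purine metabolism fell in 12 of 19 genes (13 adjusted over the list alone, camera adjusted p = 7.86e-06, adjusted p = 0.0262 with an estimated correlation). Its strongest members by p were MTHFD2 (-1.01 ± 0.14), a mitochondrial folate enzyme, and the purine synthesis enzymes PAICS (-0.76 ± 0.095) and IMPDH2 (-0.75 ± 0.13).

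Ribosomal protein genes were lower by small amounts, with 38 of 41 called (40 adjusted over the list alone), a median of -0.29 and examples RPS12 (-0.49 ± 0.086), RPL37 (-0.48 ± 0.084) and RPL19 (-0.42 ± 0.07). The list had a camera adjusted p = 5.33e-16, but adjusted p = 0.379 with an estimated correlation. Oxidative phosphorylation genes fell in 17 of 33 members and rose in 1 (20 and 2 adjusted over the list alone), with SDHD at -0.44 ± 0.072, NDUFV2 at -0.39 ± 0.065 and CYC1 at -0.37 ± 0.068 (camera adjusted p = 7.86e-06, adjusted p = 0.477 with an estimated correlation). In the cell cycle list 4 of 30 genes rose (2 adjusted over the list alone), among them the replication helicase subunits MCM2 (0.62 ± 0.12), MCM5 (0.37 ± 0.13) and MCM7 (0.34 ± 0.10), with a camera adjusted p = 0.0358, adjusted p = 0.843 with an estimated correlation. Of 11 genes reported for MLL, 5 fell (7 lower and 1 higher adjusted over the list alone, camera adjusted p = 9.04e-05, adjusted p = 0.0262 with an estimated correlation), including PBX3 at -1.13 ± 0.11. MLL is in the reference, which enlarges this fall. The list had a mean score of -0.53 in TEL-AML1, 1.53 in MLL and between -0.38 and 0.15 in the remaining groups. ETV6, a partner in the fusion, was at -0.19 ± 0.14 (adjusted p = 0.356) and did not pass the test. IKZF1, a lymphoid transcription factor, was higher by 0.34 ± 0.12, while PAX5, CD34 and CRLF2 did not pass, at 0.22, -0.44 and 0.039.

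BCR-ABL samples showed higher expression of some genes listed as STAT5 and cytokine feedback targets, a list that shares members with the one reported for BCR-ABL. Erythroid and cell cycle lists were called lower by camera with the preset correlation alone, both at adjusted p = 0.372 with an estimated correlation. SPATS2L was 9.50-fold higher than in the other groups (3.25 ± 0.39, n = 20) and PON2, a paraoxonase, 5.96-fold higher (2.57 ± 0.27), each above the median of the other samples in 20 of 20. JCHAIN, the immunoglobulin joining chain, rose by 2.37 ± 0.42, the collagen gene COL6A3 by 2.01 ± 0.29, CCND2, which drives entry into the cell cycle, by 1.92 ± 0.23, and EPAS1, a hypoxia-inducible factor, by 1.86 ± 0.30. The largest falls were in BAHCC1 (-1.89 ± 0.30), ALAS2, the erythroid enzyme of heme synthesis (-1.67 ± 0.52), carbonic anhydrase CA2 (-1.53 ± 0.43), LAMP5 (-1.51 ± 0.33), the Wnt receptor FZD2 (-1.44 ± 0.22) and PCDH9 (-1.40 ± 0.45). MLL, where LAMP5 was far higher, is in the reference, which enlarges the LAMP5 fall.

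The genes joined in the fusion moved apart, with ABL1 higher by 0.79 ± 0.10 (adjusted p = 2.13e-09, 20 of 20 samples) and BCR lower at -0.41 ± 0.12 (adjusted p = 0.0214, 18 of 20 samples) in limma with Benjamini-Hochberg adjustment. The array reports each gene by a probe set whose place relative to the breakpoint is not given in the sources used here. CD34, a progenitor surface protein, was higher by 1.01 ± 0.30, and IKZF1 (-0.13 ± 0.15), PAX5 (-0.46) and CRLF2 (-0.25) did not pass. In all, 812 genes were called, 385 higher and 427 lower, and 85 and 23 of them differed at least 2-fold. With each array centred on its median, the share of higher genes among those called was 57.8%, against 47.4% without that step.

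Of 17 genes reported for BCR-ABL or kinase-activated leukemia, 14 rose (15 adjusted over the list alone, camera adjusted p = 3.93e-29, adjusted p = 4.92e-10 with an estimated correlation), which again is not independent evidence. STAT5 and cytokine feedback targets rose in 5 of 15 members (6 adjusted over the list alone, camera adjusted p = 2.75e-07, adjusted p = 8.79e-06 with an estimated correlation). Among them were the interleukin 2 receptor chain IL2RA (1.04 ± 0.25) and the phosphatase DUSP6 (1.08 ± 0.26), and 5 of the 16 genes fixed for this list stood in other lists too. CISH, SOCS2, IL2RA and CCND2 are also in the reported BCR-ABL list, so the rise of the STAT5 list is not independent evidence either. Its highest median in any comparison was 0.24. MHC class II genes rose in 4 of 12 (7 adjusted over the list alone), with HLA-DQB1 at 0.76 ± 0.24, the transactivator CIITA at 0.50 ± 0.16 and the invariant chain CD74 at 0.47 ± 0.12 (camera adjusted p = 1.45e-06, adjusted p = 0.216 with an estimated correlation). Glucocorticoid response genes rose in 4 of 13 (4 adjusted over the list alone), with FKBP5 at 1.19 ± 0.38, KLF9 at 0.98 ± 0.22 and TXNIP at 0.49 ± 0.15 (camera adjusted p = 0.0241, adjusted p = 0.372 with an estimated correlation). The cell cycle list fell in 9 of 30 genes (22 adjusted over the list alone), for example the mitotic checkpoint kinases TTK (-0.56 ± 0.16) and BUB1B (-0.52 ± 0.11), with a camera adjusted p = 7.84e-11, adjusted p = 0.372 with an estimated correlation. Erythroid markers, which include ALAS2, the anion exchanger SLC4A1 (-1.35 ± 0.41) and the factor KLF1 (-0.87 ± 0.26), fell in 3 of 8 (8 adjusted over the list alone). This list moved beside the cell cycle list with a median of -1.12 (camera adjusted p = 5.54e-05, adjusted p = 0.372 with an estimated correlation). Ribosomal protein genes had a median of 0.19 with 2 of 41 higher (8 adjusted over the list alone), RPS29 and RPS18 (camera adjusted p = 6.66e-11, adjusted p = 0.461 with an estimated correlation). Genes reported for TEL-AML1 fell in 3 of 14 and rose in 1 (7 and 1 adjusted over the list alone), with PTPRK at -1.16 ± 0.31, KCNN1 at -0.82 ± 0.17 and CD27 at 1.06 ± 0.24 (camera adjusted p = 0.00749, adjusted p = 0.372 with an estimated correlation). TEL-AML1 is in the reference here, which lowers this list. Its mean score of -0.29 in BCR-ABL lay within the range of all groups but TEL-AML1, -0.47 to -0.13.

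BCR-ABL was also compared with the mean of Hyperdip47-50, Pseudodip and Other, 3 of the groups whose labels name no fusion. The leading genes were SPATS2L (2.80 ± 0.41), PON2 (2.78 ± 0.29), JCHAIN (2.35 ± 0.46) and NT5E, the ectonucleotidase CD73 (2.21 ± 0.39). The largest falls were in ALAS2 (-2.14 ± 0.56), CA2 (-1.97 ± 0.46), BAHCC1 (-1.88 ± 0.32) and IGLL1, part of the surrogate light chain (-1.88 ± 0.39). Limma called 790 genes, 386 higher and 404 lower, 92 and 37 of them at least 2-fold, and with each array centred on its median 364 higher and 337 lower. STAT5 and cytokine feedback targets rose in 5 of 15 (6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.000101, adjusted p = 0.00110 with an estimated correlation), including the cytokine signal suppressor SOCS2, higher by 1.16 ± 0.26 in 20 of 20 samples. SOCS2 is also in the reported BCR-ABL list. The reported BCR-ABL list rose in 15 of 17 genes (15 adjusted over the list alone, camera adjusted p = 4.60e-24, adjusted p = 1.80e-08 with an estimated correlation), which is not independent evidence. Erythroid genes fell in 7 of 8 (8 adjusted over the list alone), among them SLC4A1 (-1.66 ± 0.44) and KLF1 (-1.12 ± 0.28), with a camera adjusted p = 1.92e-07, adjusted p = 0.185 with an estimated correlation. Cell cycle genes fell in 6 of 30 (16 adjusted over the list alone), with MCM7 at -0.49 ± 0.13 and BIRC5 at -0.41 ± 0.12 (camera adjusted p = 7.36e-09, adjusted p = 0.436 with an estimated correlation). Mature B cell markers rose in 4 of 14 (6 adjusted over the list alone), with CD27 at 1.24 ± 0.26, CD69 at 1.05 ± 0.32 and BANK1 at 1.02 ± 0.29 (camera adjusted p = 0.0494, adjusted p = 0.532 with an estimated correlation). MHC class II genes rose in 4 of 12 (8 adjusted over the list alone), HLA-DMB by 0.77 ± 0.20 (camera adjusted p = 3.66e-07, adjusted p = 0.154 with an estimated correlation). The ribosomal list rose in 1 of 41 genes, RPS29 (0 adjusted over the list alone, median 0.095, camera adjusted p = 0.00349, adjusted p = 0.793 with an estimated correlation). With the T cell, monocyte, erythroid and neutrophil granule scores as covariates the call count was 506 genes. The ribosomal median then turned to -0.0023 and the list was not called.

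MLL samples had lower levels of several B-cell precursor genes and higher levels of MEIS1 than the other groups. LAMP5, a lysosome-associated membrane protein, was 41.4-fold higher (5.37 ± 0.39, n = 13) and LGALS1 18.9-fold higher (4.24 ± 0.54), above the median of the other samples in 13 of 13 samples each. MEIS1, a homeobox cofactor, rose by 3.55 ± 0.27 (12 of 13 samples), the stem cell marker PROM1 by 2.44 ± 0.42, the ETS factor SPIB by 2.40 ± 0.34, and NPTX2 by 2.21 ± 0.32. MME, which encodes the antigen CD10, was 27.2-fold lower (-4.76 ± 0.44, 13 of 13 samples). STK32B (-3.68 ± 0.37), DNTT, the terminal transferase of V(D)J joining (-3.15 ± 0.35), ELK3 (-3.07 ± 0.29), SMAD1 (-2.98 ± 0.56) and the lipoxygenase ALOX5 (-2.89 ± 0.39) also fell. The reference includes TEL-AML1, where SMAD1 was higher, which enlarges the SMAD1 fall.

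Limma called 997 genes, 504 higher and 493 lower, with 85 and 138 at least 2-fold different. The balance turned with each array centred on its median, at 400 higher and 518 lower. B-cell precursor markers fell in 6 of 16 (7 adjusted over the list alone, camera adjusted p = 1.52e-06, adjusted p = 0.112 with an estimated correlation), with the recombinase RAG1 at -1.80 ± 0.37 beside MME and DNTT. The list reported for MLL rose in 10 of 11 genes (10 adjusted over the list alone, camera adjusted p = 9.14e-23, adjusted p = 6.52e-10 with an estimated correlation), including the splicing factor MBNL1 at 1.22 ± 0.15, and is not independent evidence. KMT2A itself was lower, at -0.82 ± 0.16 (adjusted p = 4.33e-05, limma with Benjamini-Hochberg adjustment), and all 5 of its other probe sets had the same direction. FLT3, a receptor tyrosine kinase, was higher by 1.01 ± 0.35 and CD34 lower at -1.13 ± 0.36. IKZF1 (0.30), PAX5 (0.31) and CRLF2 (-0.75) did not pass. STAT5 and cytokine feedback targets fell in 5 of 15 (6 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00209, adjusted p = 0.0119 with an estimated correlation). Its members included CCND2 at -2.33 ± 0.28, CISH at -0.96 ± 0.19 and the survival gene BCL2L1 at -0.79 ± 0.20. CCND2 and CISH also stand in the list reported for BCR-ABL, a group that is in the reference here. Genes reported for BCR-ABL fell in 5 of 17 (11 adjusted over the list alone, camera adjusted p = 3.25e-09, adjusted p = 0.00135 with an estimated correlation), among them the adaptor GAB1 (-1.17 ± 0.18).

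Several lists called in MLL were lost with an estimated correlation. Interferon response genes fell in 3 of 23 (5 adjusted over the list alone), namely IFI44 (2.00-fold lower), IFIT3 (-0.72 ± 0.20) and IFIT2 (-0.53 ± 0.18), with a camera adjusted p = 0.000603, adjusted p = 0.596 with an estimated correlation. MHC class II genes had a median of -0.55 with 1 of 12 lower, HLA-DRB1 at -0.64 ± 0.20 (4 adjusted over the list alone, camera adjusted p = 0.00165, adjusted p = 0.449 with an estimated correlation). Genes reported for TEL-AML1 fell in 3 of 14 (7 adjusted over the list alone), with CD27 at -1.35 ± 0.29, PCLO at -1.30 ± 0.35 and FUCA1 at -0.54 ± 0.17 (camera adjusted p = 7.06e-05, adjusted p = 0.0770 with an estimated correlation). The reference includes TEL-AML1, which enlarges these falls. PCLO averaged a log2 signal of 7.28 in MLL, 11.76 in TEL-AML1 and between 7.86 and 8.32 in the remaining groups. No erythroid gene passed over all genes and 3 of 8 were lower adjusted over the list alone, with EPB42 at -1.43 ± 0.55 and HBD at -1.35 ± 0.55 (camera adjusted p = 0.00406, adjusted p = 0.596 with an estimated correlation). Oxidative phosphorylation genes moved both ways, with 1 higher and 1 lower, CYC1 at 0.35 ± 0.10 and SDHA at -0.54 ± 0.14, among 33 measured (1 higher and 1 lower adjusted over the list alone, median 0.089, camera adjusted p = 0.0455, adjusted p = 0.765 with an estimated correlation).

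Hyperdip>50 samples had higher expression of the genes of several chromosomes. The interferon response list was also called higher, with the preset correlation alone (adjusted p = 0.535 with an estimated correlation). SH3BP5 was 4.92-fold higher (2.30 ± 0.28, n = 28). The interferon-induced gene IFI44L rose by 2.27 ± 0.46, the lipid antigen presenter CD1C by 2.16 ± 0.31, the interleukin 3 receptor chain IL3RA by 2.12 ± 0.26 (26 of 28 samples), PROM1 by 1.98 ± 0.31 and the cytokine-like gene CYTL1 by 1.83 ± 0.35. Falls were largest for PCDH9 (-2.59 ± 0.40), the sodium channel SCN3A (-2.45 ± 0.41), the kinase anchor AKAP12 (-2.08 ± 0.33), TCL1B (-2.04 ± 0.50), the phosphatase PTPRK (-1.72 ± 0.27) and STAP1 (-1.69 ± 0.29). Limma called 1958 genes, 1052 higher and 906 lower, of which 78 and 29 differed at least 2-fold. The counts were 1084 and 668 with each array centred on its median, while the balance turned with the mean over probe sets (983 and 1012), every probe set (1441 and 1506) and array weights (1242 and 1248).

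Of 23 chromosomes, camera called 19, and the higher ones were X, 21, 14, 10, 18, 6, 17 and 4. Chromosome 21 had a median log2 difference of 0.30 with 63 genes higher and 1 lower (camera adjusted p = 4.64e-20, and adjusted p = 1.08e-06 with an estimated correlation), for example PIGP (0.85 ± 0.087) and the kinase DYRK1A (0.65 ± 0.076). Chromosome X had a median of 0.22 with 175 of 420 genes higher (camera adjusted p = 1.35e-25, and adjusted p = 1.08e-06 with an estimated correlation), among them FTSJ1 (0.81 ± 0.084) and PSMD10 (0.98 ± 0.11). Chromosome 14 stood at 0.16 (126 of 361 genes higher, including the repair enzyme PARP2 at 0.54 ± 0.062), chromosome 18 at 0.14 (43 genes, CHMP1B at 0.43 ± 0.073) and chromosome 10 at 0.13 (113 of 407, the lysosomal activator PSAP 2.30-fold higher). Chromosome 6 (0.079, RRAGD at 1.04 ± 0.15), chromosome 17 (0.064, TTC19 at 0.49 ± 0.075) and chromosome 4 (0.061, RBPJ at 0.49 ± 0.071) were smaller shifts. With an estimated correlation, 7 of the 8 held, the weakest being chromosome 17 at adjusted p = 0.0435, and chromosome 4 had an adjusted p = 0.0904 with an estimated correlation. The other 11 were relatively lower, and of these chromosomes 2, 13 and 16 held with an estimated correlation, at medians of -0.088, -0.11 and -0.098, with the transcription factor ELF1 (-0.72 ± 0.11) and the metallothionein MT1X (-1.35 ± 0.21) as examples. Chromosomes 1, 3, 5, 7, 15, 19, 20 and 22 were lost, at adjusted p = 0.118, 0.0635, 0.118, 0.113, 0.0883, 0.0883, 0.0927 and 0.0883 with an estimated correlation. All shifts are relative to the other genes of the same arrays, which were scaled to a common mean.

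**Figure D2:**
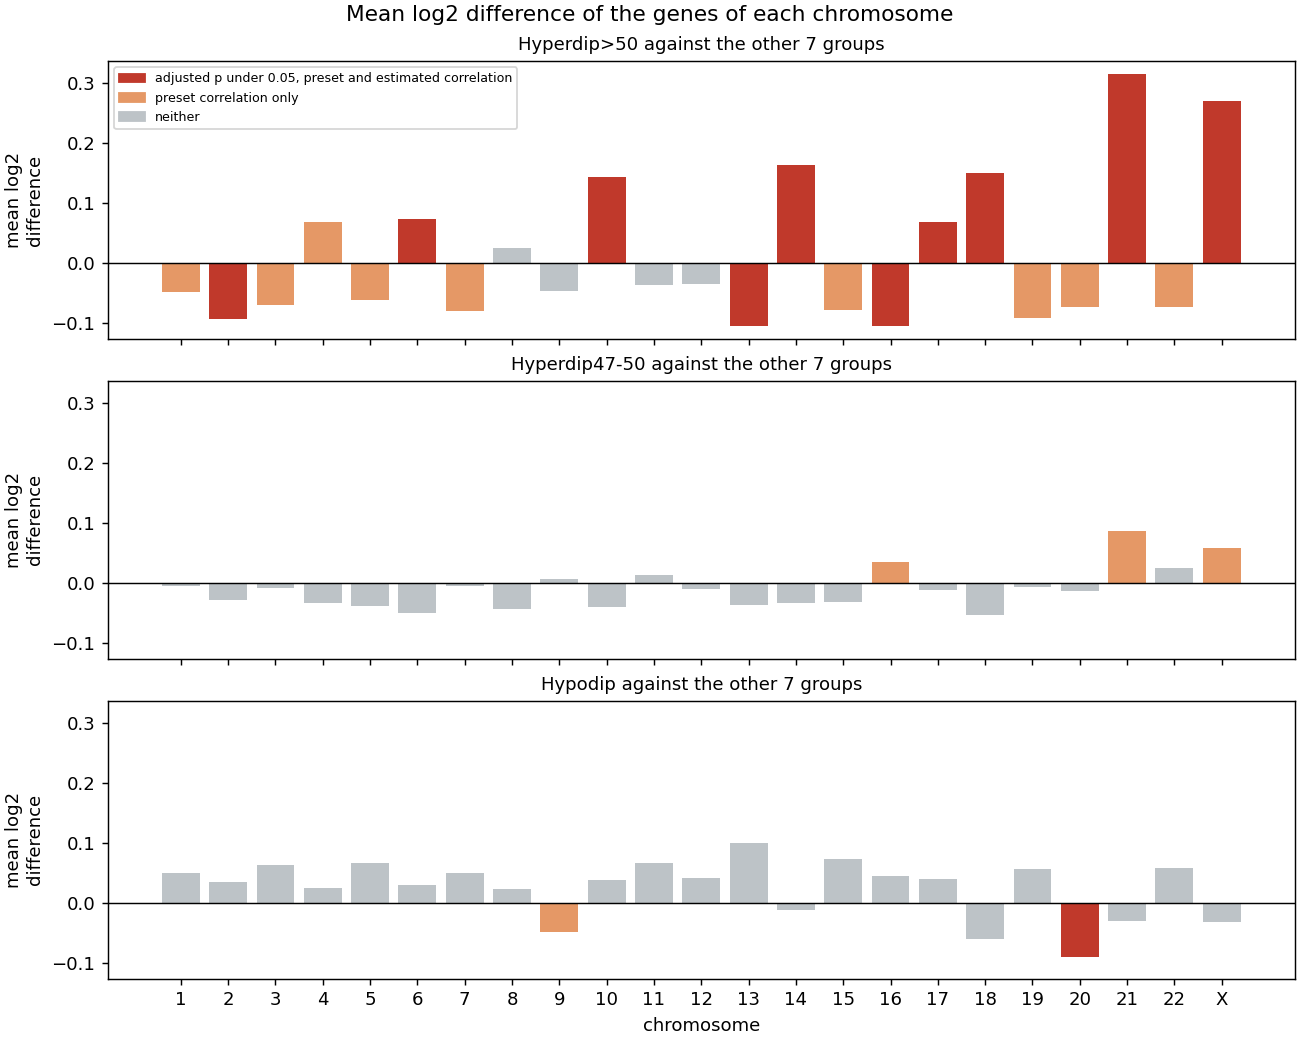
Mean log2 difference of the genes of each chromosome in Hyperdip>50, Hyperdip47-50 and Hypodip against the other 7 groups, 1 bar per chromosome. Red bars passed camera with both correlations and orange bars with the preset one alone. Chromosomes X and 21 stood highest in Hyperdip>50, with means of 0.27 and 0.32.

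The interferon response list rose in 17 of 23 genes in Hyperdip>50 (18 adjusted over the list alone) with a median of 0.58, and its examples were the antiviral GTPase MX1 (1.71 ± 0.25) and the factor IRF9 (0.65 ± 0.13). The list had a camera adjusted p = 9.44e-11, but adjusted p = 0.535 with an estimated correlation. Genes reported for TEL-AML1 fell in 5 of 14 (6 adjusted over the list alone), including ARHGEF4 at -0.76 ± 0.21 and BIRC7 at -0.58 ± 0.17 (camera adjusted p = 0.0133, adjusted p = 0.535 with an estimated correlation). The reference includes TEL-AML1, which enlarges these falls. ARHGEF4 averaged a log2 signal of 7.17 in Hyperdip>50, 10.65 in TEL-AML1 and between 7.19 and 7.65 in the remaining groups. The B-cell factors PAX5 and IKZF1 were lower, at -0.61 ± 0.14 and -0.37 ± 0.13, while CD34 (0.36) and CRLF2 (-0.082) did not pass. The 3' to 5' ratios of both control genes averaged highest in this group, at 0.37 ± 0.70 (SD, n = 28) for GAPDH.

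Hyperdip>50 was compared with Hyperdip47-50 to separate groups that the labels tell apart by the range of the chromosome number. PROM1 stood 6.41-fold (2.68 ± 0.45, n = 28 and 16) and IL3RA 4.58-fold (2.19 ± 0.38) above Hyperdip47-50. TBC1D9 (2.07 ± 0.46), MS4A6A (1.90 ± 0.36), ARHGEF10 (1.70 ± 0.40) and CYB5R2 (1.60 ± 0.39) followed. PCDH9 (-2.23 ± 0.59), AKAP12 (-2.08 ± 0.48), SYK, a kinase of B-cell receptor signalling (-1.52 ± 0.26), IGF2R (-1.44 ± 0.30), PTPRK (-1.42 ± 0.40) and HPS4 (-1.24 ± 0.22) were lower. Limma called 353 genes, 240 higher and 113 lower, 50 and 11 of them at least 2-fold, and 220 with each array centred on its median.

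Of 23 chromosomes 17 were called in this comparison, 9 higher and 8 lower, and 8 held with an estimated correlation. The 9 others had adjusted p = 0.0540 to 0.203 with an estimated correlation. Chromosomes 14 (0.19, 45 of 361 genes higher), X (0.18, 34 of 420), 18 (0.18, 15 genes), 21 (0.17, 15 genes), 10 (0.17, 25 of 407) and 6 (0.11, 27 of 613) were higher with both correlations, and chromosomes 16 (-0.13) and 22 (-0.085) lower. Interferon response genes rose in 2 of 23, OAS1 at 1.16 ± 0.32 and MX1 at 1.29 ± 0.36 (8 adjusted over the list alone, camera adjusted p = 6.30e-08, adjusted p = 0.799 with an estimated correlation). Stem and progenitor genes rose in 3 of 16, with FLT3 2.83-fold higher and the ETS factor ERG at 1.05 ± 0.31 beside PROM1 (4 adjusted over the list alone, camera adjusted p = 0.0172, adjusted p = 0.423 with an estimated correlation). No cell cycle gene passed, with a list median of -0.17, CDC20 at -0.73 ± 0.23 and 0 lower adjusted over the list alone (camera adjusted p = 0.0399, adjusted p = 0.865 with an estimated correlation). CRLF2 (-0.94), IKZF1 (-0.47), PAX5 (-0.29) and CD34 (0.36) did not pass.

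In Hypodip many of the lower genes lay on chromosomes 9 and 20. Of the 24 genes called lower by limma, 12 lay on chromosome 9, where 410 genes were tested, and 6 on chromosome 20, where 302 were tested. VCP, an ATPase that extracts proteins for degradation, was 3.01-fold lower (-1.59 ± 0.19, 7 of 7 samples), and STOML2, a mitochondrial membrane protein, fell by 1.07 ± 0.17, both on chromosome 9. On chromosome 20 the engulfment gene ELMO2 (-1.21 ± 0.29), ERGIC3 (-0.83 ± 0.15) and RPN2, a subunit of the glycosylation complex (-0.79 ± 0.16), were lower. SMAD1 (-2.96 ± 0.74), DCHS1 (-1.78 ± 0.34), the histone demethylase KDM5B (-1.37 ± 0.27) and the HSP90 cochaperone FKBP4 (-1.26 ± 0.30) also fell. The reference includes TEL-AML1, where SMAD1 was higher, which enlarges the SMAD1 fall. All 6 higher genes were NAV2 (1.56 ± 0.35), RASAL1 (1.31 ± 0.32), PIP5K1B (1.19 ± 0.28), TTN (1.18 ± 0.30), HESX1 (1.18 ± 0.26) and SMYD2 (0.97 ± 0.23). In all 30 genes were called, 5 higher and 10 lower by at least 2-fold.

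Camera called chromosome 20 (median -0.077, camera adjusted p = 6.56e-06, and adjusted p = 0.0242 with an estimated correlation) and chromosome 9 (median -0.001, mean -0.048, camera adjusted p = 0.0167, and adjusted p = 0.564 with an estimated correlation). Without Hypodip replicate 3 the adjusted p of chromosome 9 was 0.0915 and without replicate 5 it was 0.0561, in a range of 0.00753 to 0.564 over the alternatives run for chromosomes. Its mean was -0.020 without replicate 3, -0.031 without replicate 6 and -0.078 without replicate 4. The mean of chromosome 20 was -0.089, and it was -0.052 without replicate 6 and -0.058 without replicate 9, with adjusted p from 2.16e-08 to 0.0242 over the same alternatives. The gene count lay between 14 and 38 with 1 sample left out, at 14 without replicate 26 and 15 without replicate 4. In 14 genes reported for TEL-AML1 the median was -0.31 (camera adjusted p = 0.00553, adjusted p = 0.436 with an estimated correlation), with PTPRK at 1.27 ± 0.49 and TCFL5 at -1.47 ± 0.42. TEL-AML1 is in the reference, which lowers this list. Its mean score of -0.24 in Hypodip lay within the range of all groups but TEL-AML1, -0.47 to -0.13. The glucocorticoid list had a median of -0.27 (FKBP5 -0.99, camera adjusted p = 0.00452, adjusted p = 0.436 with an estimated correlation). Interferon response genes stood at -0.29 (MX1 -0.82, camera adjusted p = 0.00452, adjusted p = 0.695 with an estimated correlation) and MHC class II genes at -0.24 (CIITA -0.49, camera adjusted p = 0.0293, adjusted p = 0.695 with an estimated correlation). Neutrophil granule markers had a median of -0.43, with the elastase ELANE at -1.01 and PRTN3 at -0.94 (camera adjusted p = 0.0297, adjusted p = 0.695 with an estimated correlation). No member of these 5 lists passed over all genes, and adjusted over the list alone 1 gene of the TEL-AML1 list passed and 0 of the others. CD34 (-0.75), IKZF1 (-0.38) and PAX5 (0.34) did not pass, nor did CRLF2 at 0.32 ± 0.41, which was at -0.21 without Hypodip replicate 9.

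In Hyperdip47-50 only ASMTL, a gene near 1 end of chromosome X, was called by limma, at -0.66 ± 0.12 (adjusted p = 0.00365, n = 16, 14 of 16 samples), while 835 genes had an unadjusted p under 0.05. CRLF2, a cytokine receptor chain, was at 1.00 ± 0.28 (adjusted p = 0.221), with a wide spread of 1.89 (SD) between samples. The SD of ASMTL in this group was 0.71, while both SEs rest on the spread shared by all 8 groups. Chromosomes 21, X and 16 were called higher by camera, at medians of 0.089, 0.069 and 0.035, with camera adjusted p = 0.00102, 0.00102 and 0.0453, and each had an adjusted p = 0.338 with an estimated correlation. Erythroid markers had a median of 0.82 with 0 of 8 called over all genes and 2 adjusted over the list alone, EPB42 at 1.38 ± 0.50 and CA1 at 1.10 ± 0.41 (camera adjusted p = 7.50e-06, adjusted p = 0.434 with an estimated correlation). The cell cycle list stood beside them at 0.20 with 0 of 30 genes called by either adjustment, CCNA2 at 0.62 ± 0.21 and CDC20 at 0.59 ± 0.20 (camera adjusted p = 3.21e-08, adjusted p = 0.604 with an estimated correlation). Genes reported for MLL had a median of -0.34 (LGALS1 -1.12, camera adjusted p = 0.0117, adjusted p = 0.344 with an estimated correlation). Those for TEL-AML1 had a median of -0.22 (PCLO -0.55, camera adjusted p = 0.0399, adjusted p = 0.604 with an estimated correlation), and both lists had 0 members called over all genes or adjusted over the list alone. TEL-AML1 and MLL are in the reference, which lowers both lists. PCLO averaged a log2 signal of 7.95 in Hyperdip47-50, within the range of all groups but TEL-AML1, 7.28 to 8.32, so its difference came from TEL-AML1. CD34 (-0.052), IKZF1 (0.16) and PAX5 (-0.28) did not pass. ASMTL was no longer called without the 3 arrays that stood apart (adjusted p = 0.155) or with the mean over its probe sets (adjusted p = 0.366), in a range of 0.00024 to 0.366 over the alternatives.

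In Pseudodip samples limma called 6 genes. The metallothionein MT1X rose by 1.33 ± 0.26 (14 of 16 samples) and the splicing factor SRSF8 by 0.57 ± 0.11. IRAK3, an inhibitor of Toll-like receptor signalling, fell by 1.33 ± 0.28, and TSPAN13 (-0.83 ± 0.16), THEMIS2 (-0.80 ± 0.16) and SYPL1 (-0.67 ± 0.14) were lower. Camera called 5 lists lower and 3 higher with the preset correlation, none with an estimated one, and no member of them passed over all genes. The mature B cell list had a median of -0.41 (3 of 14 lower adjusted over the list alone, BANK1 -1.05, IGHD -0.95, camera adjusted p = 0.000247, adjusted p = 0.129 with an estimated correlation). MHC class II genes had a median of -0.35 (5 of 12 lower adjusted over the list alone, HLA-DMB -0.88, camera adjusted p = 6.25e-05, adjusted p = 0.256 with an estimated correlation). Stem and progenitor genes stood at -0.25 (1 of 16 adjusted over the list alone, PROM1 -1.55, camera adjusted p = 0.00590, adjusted p = 0.129 with an estimated correlation). The reported MLL list was at -0.19 (2 of 11 adjusted over the list alone, camera adjusted p = 0.00140, adjusted p = 0.129 with an estimated correlation). The reported BCR-ABL list was at -0.18 (0 of 17 adjusted over the list alone, PON2 -0.69, camera adjusted p = 0.0341, adjusted p = 0.577 with an estimated correlation). MLL and BCR-ABL are in the reference, which lowers the lists reported for them. Small shifts upward were found for oxidative phosphorylation (0.079, SDHA 0.36, camera adjusted p = 0.00111, adjusted p = 0.676 with an estimated correlation) and ribosomal protein genes (0.052, RPL24 0.20, camera adjusted p = 0.0164, adjusted p = 0.760 with an estimated correlation). Cell cycle genes stood at 0.10 (MCM4 0.24, camera adjusted p = 0.0208, adjusted p = 0.760 with an estimated correlation), and these 3 lists had 0 members called by either adjustment. Chromosomes X (-0.10, camera adjusted p = 3.88e-05, and adjusted p = 0.159 with an estimated correlation) and 21 (-0.11, camera adjusted p = 0.000985, and adjusted p = 0.182 with an estimated correlation) were called lower. So was chromosome 4 (-0.06, camera adjusted p = 0.00669, and adjusted p = 0.265 with an estimated correlation), and chromosome 20 was called higher (0.054, camera adjusted p = 0.000985, and adjusted p = 0.159 with an estimated correlation). Hyperdip>50 is in the reference, with mean chromosome scores of 0.24 for X and 0.28 for 21, which lowers both here. On X, Pseudodip scored -0.089, BCR-ABL -0.068 and MLL -0.069. On 21 the scores were -0.094, -0.082 and -0.075 in the same order. CD34, CRLF2, IKZF1 and PAX5 did not pass, at -0.16, -0.091, -0.093 and 0.24. The count ran up to 33 genes with array weights.

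In the samples labelled Other, AGAP1, a GTPase-activating protein, was 3.70-fold above the mean of the other groups (1.89 ± 0.33, n = 25), the receptor phosphatase PTPRM 3.61-fold (1.85 ± 0.33), the sulfotransferase CHST2 3.49-fold (1.80 ± 0.28) and SMAD1 3.27-fold (1.71 ± 0.42), although the SMAD1 mean was higher still in TEL-AML1. AGAP1 was above the median of the other samples in 17 of 25 and PTPRM in 21 of 25. The matricellular gene CCN2 (-1.42 ± 0.34), the adhesion receptor ADGRG1 (-1.29 ± 0.28), KHDRBS3 (-1.28 ± 0.26) and CRIP1 (-1.27 ± 0.32) fell, and CD34 was higher by 1.16 ± 0.27. Limma called 135 genes, 70 higher and 65 lower, 18 and 10 of them at least 2-fold, and 241 with array weights.

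Immediate early and stress genes rose in 2 of 16 in Other (11 adjusted over the list alone), JUNB by 0.73 ± 0.17 and EGR1 by 0.95 ± 0.27, with a camera adjusted p = 2.60e-08, adjusted p = 0.0714 with an estimated correlation. Ribosomal protein genes had a median of 0.20 with 1 of 41 higher (24 adjusted over the list alone), RPS6 at 0.31 ± 0.083 (camera adjusted p = 5.23e-20, adjusted p = 0.276 with an estimated correlation). The cell cycle list had a median of -0.26 with 0 of 30 genes called by either adjustment, KIF11 at -0.45 ± 0.16 (camera adjusted p = 1.29e-09, adjusted p = 0.376 with an estimated correlation). The erythroid markers stood higher beside these lists, with a median of 0.59 (HBD 0.75, camera adjusted p = 0.00164, adjusted p = 0.516 with an estimated correlation). Interferon response genes stood at 0.16 (IFI44L 1.27, camera adjusted p = 0.00233, adjusted p = 0.612 with an estimated correlation). Oxidative phosphorylation was at -0.059 (NDUFA1 -0.28, camera adjusted p = 0.00362, adjusted p = 0.612 with an estimated correlation), and these 3 lists had 0 members called by either adjustment. Reported lists were lower. For BCR-ABL 1 of 17 genes fell, PON2 at -1.01 ± 0.25 (4 adjusted over the list alone, camera adjusted p = 0.00119, adjusted p = 0.260 with an estimated correlation). For MLL 1 of 11 fell, the actin capping gene CAPG at -0.69 ± 0.16 (1 adjusted over the list alone, camera adjusted p = 0.00630, adjusted p = 0.276 with an estimated correlation), and for TEL-AML1 0 of 14 (2 adjusted over the list alone, camera adjusted p = 0.00370, adjusted p = 0.323 with an estimated correlation). These reported lists are not independent evidence, and the group each was named for is in the reference, which lowers the list. The TEL-AML1 list had a mean score of -0.21 in Other, within the range of all groups but TEL-AML1, -0.47 to -0.13. Single samples scored far above these means. The highest in Other was 1.65 for the TEL-AML1 list, where the lowest TEL-AML1 sample was at 1.41. It was 2.40 for the MLL list (MLL mean 1.53) and 1.69 for the BCR-ABL list (BCR-ABL mean 1.06). For the TEL-AML1 list the highest sample was at 1.74 in Pseudodip and 1.57 in Hyperdip47-50. IKZF1 (0.16), PAX5 (0.23) and CRLF2 (-0.19) did not pass.

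Among Hyperdip47-50, Pseudodip and Other, limma's F test called 0 of 10856 genes after Benjamini-Hochberg adjustment, and 778 genes had an unadjusted p under 0.05. The smallest adjusted p was 0.108. The 4 genes with the smallest p were PACSIN2, an endocytosis adaptor, CD164, a sialomucin, EHD4 and FOCAD. PACSIN2 had a mean log2 signal of 11.50 in Hyperdip47-50, 10.85 in Pseudodip and 10.70 in Other. CD164 averaged 11.63, 12.34 and 12.43 in the same order, EHD4 8.72, 8.69 and 9.62, and FOCAD 6.87, 7.35 and 8.15. The count was also 0 without trend or robust moderation, 1 with quantile normalization and 49 with array weights.

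**Figure D3:**
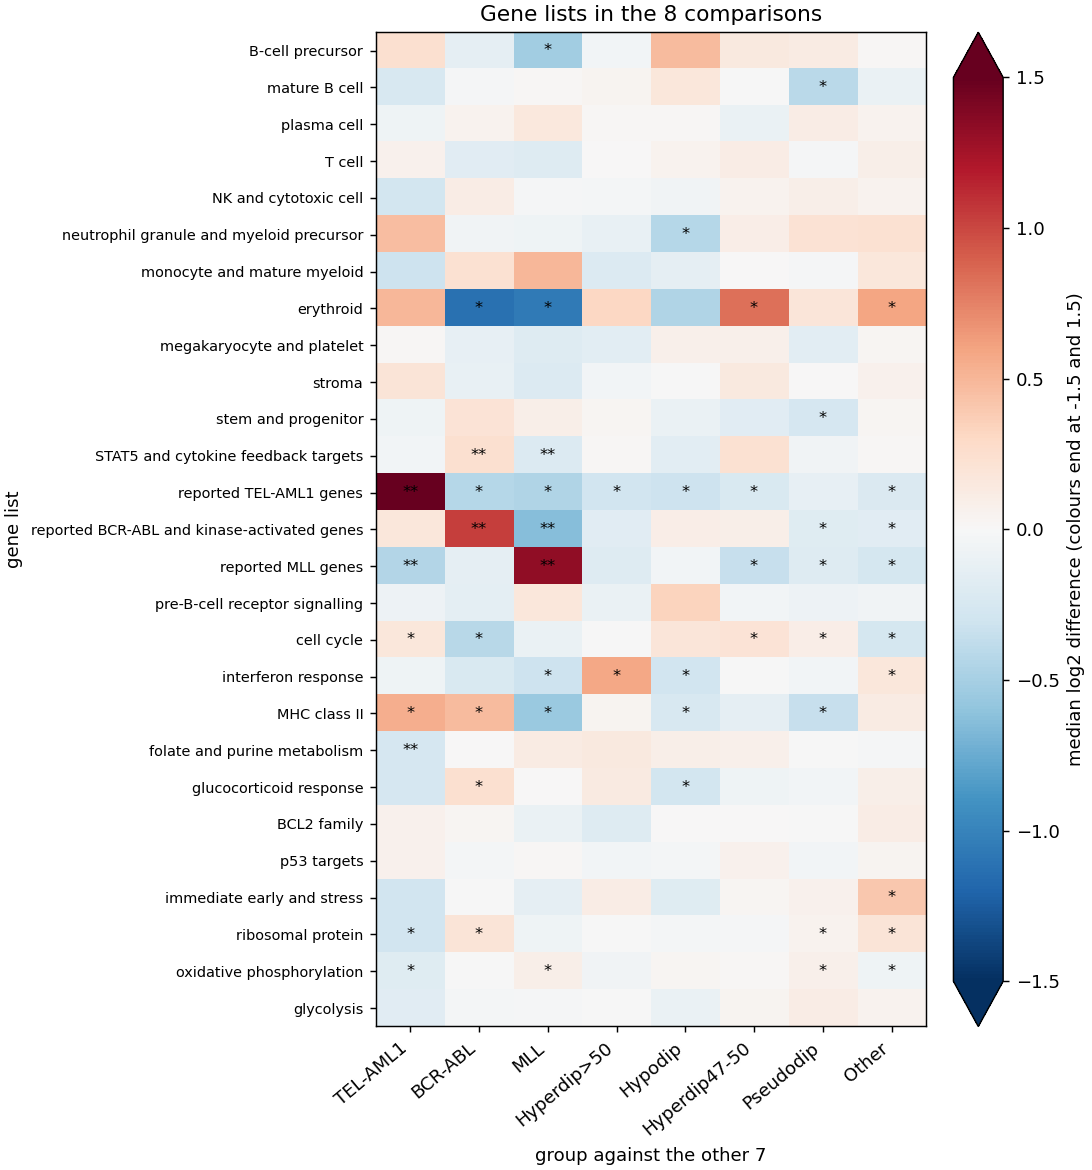
Median log2 difference of 27 gene lists (rows) in the 8 comparisons of a group with the other 7 (columns), as a colour scale that ends at -1.5 and 1.5. Stars mark lists called by camera with the preset correlation, and double stars those that also held with an estimated one, such as the STAT5 and cytokine feedback targets in BCR-ABL and MLL.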

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

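The split of chromosomes into parts, the test of 1 aberrant array and that of 1 probe set for ASMTL, and the choice of ASMTL with CRLF2 as a pattern, came after related results had been seen. It took the place of the erythroid and cell cycle pattern in BCR-ABL, so explanations were tested for 4 patterns in all, and the values of the replaced one stand under the other observations.

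In Hypodip, 34 named values were checked for a sample far from the rest, by the gap to its nearest neighbour over the whole range of 7 samples. For 3 of them the ratio exceeded Dixon's 95% critical value. Chance gives this for about 1 in 20 values, and 34 were checked without adjustment, so some of these can be chance. CRLF2 had a ratio of 0.660, with replicate 9 highest at a log2 signal of 10.36 and the next sample at 7.57. SMYD2 had 0.585, with replicate 3 highest at 12.02 and the next at 10.99. STOML2 had 0.771, with replicate 26 lowest at 7.00 and the next at 8.74.

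Of the 24 lower genes of Hypodip, 12 lay in the first part of chromosome 9, 5 in the second part of chromosome 20, 1 in its first part and 6 on other chromosomes. With each split at its widest gap between genes, the first part of chromosome 9 (111 genes) had a median of -0.27 and the second part (284 genes) 0.04, and the second part of chromosome 20 (194 genes) -0.17 against 0.02 in the first (99 genes), with adjusted p = 0.000316 and 0.00116 for the lower parts with an estimated correlation. The adjustment covers 328 tests, with all chromosomes split in this way into 41 parts of at least 5 genes, in 8 comparisons. Of these 9 passed, 2 in Hypodip and 7 in Hyperdip>50. The tests use the samples in which the lower genes had been seen. The second part of chromosome 20 was at -0.103 without Hypodip replicate 6 and between -0.134 and -0.208 without any 1 of the others, and 5 of 7 samples had a mean below 0 there. For chromosome 9, a single aberrant array and noise of weak probe sets were argued against, since the first part of chromosome 9 stayed at -0.26 or lower without any 1 sample and was at -0.47 among 48 genes above the median level. The difference between the parts of chromosome 9 was -0.31, and 6 of 7 samples had a mean below 0 in the first part, so a hypothesis is that part of chromosome 9 may be lost in some of these samples. No DNA was examined, and lower expression of neighbouring genes for another reason stays open.

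The interferon response list stood higher in Hyperdip>50. The list median was 0.58 both with and without its 2 chromosome 21 members. Leaving out 2 of 23 genes could hardly move a median, so this decides nothing about extra copies of chromosome 21. Effects of chromosome 21 genes outside the list were not tested. A few samples with a strong response were argued against, because 24 of 28 samples, or 85.7% (exact 95% interval 67.3 to 96.0), lay above the median of the other samples. The interval reaches below the bound set in advance for this share. Admixed T cells, monocytes, erythroid cells and neutrophil precursors were argued against, since the list median was 0.55 with their 4 marker scores as covariates. Further cell types, such as NK or plasma cells, were not used as covariates. The mean list score was 0.61 ± 0.80 (SD, n = 28) against -0.04 ± 0.68 (SD, n = 131), with a two-sided permutation p of 8.00e-05, while the list had an adjusted p = 0.535 with an estimated correlation. A difference in interferon signalling between these leukemias is therefore only a hypothesis, and infection or treatment before sampling was not tested.

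ASMTL was lower in Hyperdip47-50 and CRLF2, a neighbour near the end of chromosome X, stood higher without passing the test. If a stretch between CRLF2 and P2RY8 were lost in some samples, CRLF2 could be high where ASMTL, CSF2RA and IL3RA are low, but over the group CSF2RA stood at 0.027 ± 0.19 (SE, adjusted p = 0.988) and IL3RA at -0.39 ± 0.33 (adjusted p = 0.843). Spearman's rho was -0.16 (permutation p = 0.547, adjusted p = 0.729 over 4 relations) and Pearson's r -0.13 (permutation p = 0.638) over 16 samples, r being -0.033 without the 2 samples farthest out. For ASMTL alone rho was -0.45 (permutation p = 0.0828, adjusted p = 0.331) and r -0.36 (permutation p = 0.172), with rho -0.31 and r -0.198 without these 2 samples, so this stays undecided. A single aberrant array was argued against as the source of the size of the ASMTL difference, which was -0.54 or lower without any 1 sample. The call itself ended without the 3 arrays that stood apart, at -0.55 against -0.66 with all arrays. A fault of 1 probe set remains open as a possible explanation, since the other ASMTL probe sets averaged -0.26, and no finding is drawn from this pattern.

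Group labels were reassigned at random over all 8 groups, in 100 splits with the real one included. This asks whether the labels have any relation to expression. It does not ask whether 1 group alone stands out. The real split alone reached its count in TEL-AML1 (2478 genes, highest other 20), BCR-ABL (812, 175), MLL (997, 43), Hyperdip>50 (1958, 8), Other (135, 2), Hyperdip>50 against Hyperdip47-50 (353, 37), BCR-ABL against 3 groups (790, 552) and the F test over 8 groups (4019, 1), which is 1 of 100 splits each. For these counts, labels without any relation to expression were argued against. In Hypodip 2 of 100 splits reached the real count of 30 (highest other 51), and in Pseudodip 3 of 100 reached 6 (highest other 14). Both are under the bound of 5 of 100 but are not adjusted over the counts tested, so chance is not excluded for them. Nor was chance excluded for Hyperdip47-50, where 5 of 100 splits called at least 1 gene (highest other 107). Why 1 split called 107 genes, far above the real count, was not tested. Reassigned labels leave the values unchanged, so real differences between groups count there as spread within the reassigned groups. This can lower the counts of the other splits. The splits decide nothing for the F test among 3 groups, where the real count was 0 and all 100 reach it by definition (highest other 8).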

How the results depend on the processing

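Leaving out the 3 arrays that stood apart was the only alternative chosen after the data were seen, and the cause of a move was not tested except where the setting itself gives it. Of 222 called values of named genes, 160 were called under every alternative run apart from leaving out single Hypodip samples. Among the same alternatives 62 lost the call under 1 or more, and 0 reversed. This tally does not cover the fits without 1 Hypodip sample, so it does not show how stable the Hypodip genes were there. Low signals limit weak genes, whose differences shrink with the pseudocount.

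The Pseudodip count of 6 was 10 with a pseudocount of 1, 15 with the larger one, 12 with the 60th percentile, 10 with every probe set, 16 with the mean over probe sets, 33 with array weights (0.20 to 2.25) and 20 without the arrays that stood apart. The F test among 3 groups, with 0 genes, called 1 with quantile normalization, 49 with array weights and 1 without the arrays that stood apart. Hyperdip47-50, with 1 gene, had 0 with the mean over probe sets, 2 with array weights and 0 without the arrays that stood apart. Hyperdip>50 against Hyperdip47-50 had 220 with median centring, and Hyperdip>50 had 2947 with every probe set, where more features are tested. Hypodip had 46 with every probe set and, with 1 sample left out, 14 (without replicate 26), 15 (without replicate 4) to 38 (without replicate 3). Other had 241 with array weights, and BCR-ABL against 3 groups 506 with the marker scores as covariates. With an estimated correlation 10 of 62 list calls and 19 of 45 chromosome calls held. List calls were also lost, without a change of direction, 9 times with the marker scores, 8 with quantile normalization, 5 with the label number as a block, 5 without the arrays that stood apart, 2 with the smaller pseudocount, 2 with the mean over probe sets and 1 with the larger pseudocount. Among chromosome calls 2 were lost with the label number and 1 each with the marker scores, the smaller pseudocount and without the arrays that stood apart. Higher genes outnumbered lower ones under some alternatives and not under others in BCR-ABL, MLL, Hyperdip>50, Pseudodip, Other and BCR-ABL against 3 groups.

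Values of genes that were not called changed sign. IKZF1 with the mean over probe sets was at 0.013 in BCR-ABL, -0.021 in Hyperdip47-50 and 0.025 in BCR-ABL against 3 groups. CRLF2 was at -0.040 (larger pseudocount) and -0.064 (marker scores) in TEL-AML1, 0.032 (RNA quality ratios) in Pseudodip, and from -0.21 (without replicate 9) to 0.50 in Hypodip. CD34 was at 0.047 with array weights in Pseudodip, and in Hyperdip47-50 at 0.051 with the marker scores and 0.025 without the arrays that stood apart. With the marker scores as covariates, list medians were 0.016 for erythroid genes in BCR-ABL, 0.025 in MLL and 0.012 for neutrophil genes in Hypodip, as the setting removes these lists by construction, and -0.0023 for ribosomal genes in BCR-ABL against 3 groups. The share of higher genes moved from 47.4% to 57.8% in BCR-ABL with median centring, from 33.3% to 57.1% in Pseudodip with median centring, and to 20% and 53.3% there with the smaller and the larger pseudocount.

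Samples with the same label number were not paired: 362 such pairs had a mean correlation of -0.0028 and 10431 others 0.00047, and 4 samples correlated best with their own number. With this number as a block, Hypodip had 19 genes, Other 84, and CRLF2 in Pseudodip was at 0.0068.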

Other observations

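The tests of the erythroid and cell cycle lists were read by a rule changed after the result was seen, and the genes of the Other group below were set side by side after their values were seen.

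The 4 genes named as higher in Other had wide spreads there. AGAP1 averaged 9.65 ± 2.21 (SD, n = 25) in Other, 8.52 ± 2.31 (n = 16) in Pseudodip and 7.85 ± 0.77 (n = 34) in TEL-AML1. CHST2 averaged 10.75 ± 1.74 in Other, 10.03 ± 2.29 in Pseudodip and 9.29 ± 0.65 in TEL-AML1. PTPRM averaged 9.33 ± 2.08, 8.48 ± 2.13 and 7.71 ± 1.02, and SMAD1 11.58 ± 2.17, 10.16 ± 3.24 and 12.57 ± 0.69, in the same order. The difference in spread was not tested. The SEs given above for these 4 genes rest on the spread shared by all 8 groups, not on these SDs.

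PBX3, a homeobox cofactor in the list too small for camera, rose in MLL by 1.22 ± 0.17 (SE, limma adjusted p = 4.78e-09), beside MEIS1. Camera called 10 of the 27 lists in no comparison. Their lowest adjusted p was 0.279 for plasma cell markers, 0.0776 for T cell, 0.172 for NK and cytotoxic cell, 0.120 for monocyte, 0.392 for megakaryocyte and platelet and 0.204 for stroma markers. It was 0.0508 for pre-B-cell receptor signalling, 0.204 for the BCL2 family, 0.187 for p53 targets and 0.0503 for glycolysis. Some genes stood in more than 1 list. Of all genes fixed for a list, measured or not, these were 11 of 15 reported MLL genes, 6 of 18 B-cell precursor markers, 5 of 19 reported BCR-ABL genes and 0 of 15 erythroid markers.

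Lower erythroid and cell cycle genes in BCR-ABL were tested before the ASMTL pattern and then replaced by it among those weighed, after the results were known. The erythroid markers had a mean correlation of 0.825 with each other within groups. The cell cycle median was -0.41 without and -0.31 with the erythroid score as a covariate, so 75.2% was left, and between 66.3% and 79.5% with 1 sample left out. With the covariate 2 of 30 members were called lower, against 9 without, and camera gave p = 1.24e-06 at the preset correlation. Whether the cell cycle values follow the erythroid ones was left undecided.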
